A study of Cicer arietinum with 4 samples.

How the data were processed

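Ovules of chickpea cultivar ICC4958 were sampled before fertilization (closed buds) and after fertilization (half-opened flowers), with 2 libraries per group. Per the labels' protocols, total RNA was extracted with TRI reagent and sequenced as paired ends on an Illumina instrument. The authors deposited 1 table with an FPKM value for each gene and library. The submitters' processing notes name FastQC, fastp, HISAT2, Cufflinks and Cuffdiff, without version, role or order. The genome build, the annotation and any scaling between libraries are not given in the sources used here. The values were checked against the unit: they hold decimals, are never below 0 and sum to 1483040 in pre A, 1804430 in pre B, 2198000 in post A and 3574220 in post B.

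The 4 value columns name the group of each library but not which of its 2 samples it is. The libraries are therefore called pre A and pre B, post A and post B, after the ending of the column name, and the letters carry no order. Absolute depth is unknown. Relative depth was estimated from the FPKM value of 1 fragment on genes with low values (under 0.3 FPKM): 1 fragment was worth 1.82 times as much in pre B as in pre A, 0.992 times in post A and 0.901 times in post B, so low values are coarser in pre B. Over genes spanning 300 to 600 bp the lowest values gave ratios of 1.81, 0.997 and 0.917 to pre A, and over 1000 to 1500 bp 1.81, 0.998 and 0.903. On genes of about 100 bp or less the value of 1 fragment is not a measure of depth: its ratio to pre A moved with span, in pre B from 1.02 at 83 bp to 1.19 at 104 bp and in post A from 0.645 to 0.730, as a length correction that differs between libraries would do. How the authors treated short genes is not given in the sources used here. Of the 28783 genes, 7219 were listed at 0 in pre A, 7739 in pre B, 6585 in post A and 6312 in post B. A value of 0 may be a gene below detection, so no fold is given against a group listed at 0.

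Gene symbols were taken from the table and from a RefSeq gene table, matched on gene number, which found 25491 genes. That table is of another assembly, since only 203 of the matched genes have the same start. Its coordinates were not used, and the coordinates given are those of the deposited table, whose build is not stated. The chromosome number is the one most genes of the same sequence carry in the RefSeq table. Identifiers that begin with LOC made up 96.7% of the genes, and neither table gives product names. Values of members of large families, such as NAC and UDP-glycosyltransferase genes, are uncertain where copies are similar enough to share reads.

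Genes with at least 1 FPKM in 2 or more of the 4 libraries were tested, 17849 in all. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, group only, with a trend of variance on mean, and two-sided p-values were adjusted after Benjamini and Hochberg with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and a prior of 2.55. Log2 fold changes are post minus pre on the log2(FPKM + 1) scale, which understates the change of low genes, and folds are ratios of mean FPKM. Gene lists with at least 5 tested members, 14 in all, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. No called list stayed past the threshold with the estimated correlation. The smallest adjusted p of the 14 lists was then 0.868. For UDP-glycosyltransferases the estimated correlation was 0.0012, below the preset, yet the camera p rose from 0.00622 to 0.0925. The loss of that call is therefore not evidence that its members are correlated. With an estimated correlation camera rests on the 2 residual degrees of freedom, so that hardly any list could pass. Not passing it is therefore no evidence against a list. Figures were drawn with matplotlib 3.10.9.

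The tests, the rule for named genes and most alternatives were fixed before the data were examined. The 24 keyword lists fixed then need product names and could not be used. They were replaced by 20 lists built from gene symbols and RNA classes, after the symbols had been seen and before any fold change or test was computed. Symbols name few genes: 192 tested genes have one, tRNA genes left out, of which 52 rose and 27 fell. Named in each direction were the 8 genes with a symbol or synonym and the largest absolute log2 fold change among called genes, with both libraries of one group above both of the other and a mean of at least 5 FPKM in the higher group. In place of the product name that the rule asked for, a symbol was required. Added to these were, per list, the 2 called members with the largest change or, with none called, the member with the highest mean, and at most 2 identifiers without a symbol per direction. ARF11 and the members named to complete a count of 5 or fewer (NAC30, NAC18, HSFB4B, HSFA1B, HSFB2B, HSFA4C, MAPK16, MAPK12, MAPK3, MAPK11, UGT91H8, PRR59C, PRR37A, CA-EXPA3 and PAL) were chosen after their values were seen.

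The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter, a filter of 5 FPKM, quantile normalization, median-of-ratios scaling, no variance trend, a replicate block, leaving out each library, an added limit of 1 on the absolute log2 fold change and, for lists, an estimated correlation. Tests on protein-coding genes only and on genes spanning at least 300 bp only were added after the data were seen. Where a group kept 1 library, that library was assumed to vary like the other group. The filter was applied again in these runs, so genes at 1 FPKM or more only in the group that lost a library were not tested. Without post A 16877 genes were tested, without post B 16827, without pre A 17386 and without pre B 17390.

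The fit was tested on simulated values for the 17849 genes with the estimated prior spread. With 200 changed genes, 4.20% of those changed 2-fold and 58.0% of those changed 4-fold were recovered, and 3.70% of the calls were false. With 6522 changed genes, 83.8% and 96.9% were recovered, and 3.06% of the calls were false. The simulated spread was the fit's own prior and was the same in both groups. In the data the groups differed in spread. Of 10543 genes with a mean of at least 10 FPKM, 519 were at least 2-fold apart between the post-fertilization libraries. Between the pre-fertilization libraries it was 149. The simulated share of false calls is therefore not the rate for the real calls. A simulated list of 30 genes moved by 1 on the log2 scale was found, and 0 of 20 unmoved lists were called. Simulated genes varied independently, while estimated correlations in the real lists reached 0.468 for small nuclear RNA and 0.342 for auxin response factors. The simulation therefore does not give the rate of false list calls for such lists.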

Results

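Gene expression was measured by RNA sequencing in ovules of chickpea (*Cicer arietinum*), a grain legume, from the cultivar ICC4958. The ovule is the structure in the ovary that holds the egg cell and becomes the seed. Total RNA came from ovules before fertilization, taken from closed buds, and after fertilization, taken from half-opened flowers, with 2 libraries per group. The stage of the flower and fertilization therefore differ together between the groups. The libraries are called pre A, pre B, post A and post B, where the letters only tell libraries apart. The deposited table lists 28783 genes with an FPKM value in each library, and 17849 genes passed the filter on low values. By definition FPKM counts fragments per kilobase of transcript, scaled to the mapped fragments of the library. Whether the authors also scaled the values between libraries is not given in the sources used here. Sequencing depth is known only in relation to pre A, from the value of single fragments on genes with low values. Estimated in this way it was 0.549 of pre A in pre B, 1.01 in post A and 1.11 in post B.

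The libraries separated by group. Pearson's correlation of log2(FPKM + 1) across genes, which are not independent replicates, was 0.964 between the pre-fertilization libraries and 0.954 between the post-fertilization libraries. Between the groups it ranged from 0.812, for pre A with post B, to 0.858, for pre A with post A. The first principal component held 79.6% of the variance. Along it post B lay farther from the pre-fertilization libraries than post A did.

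**Figure D1:**
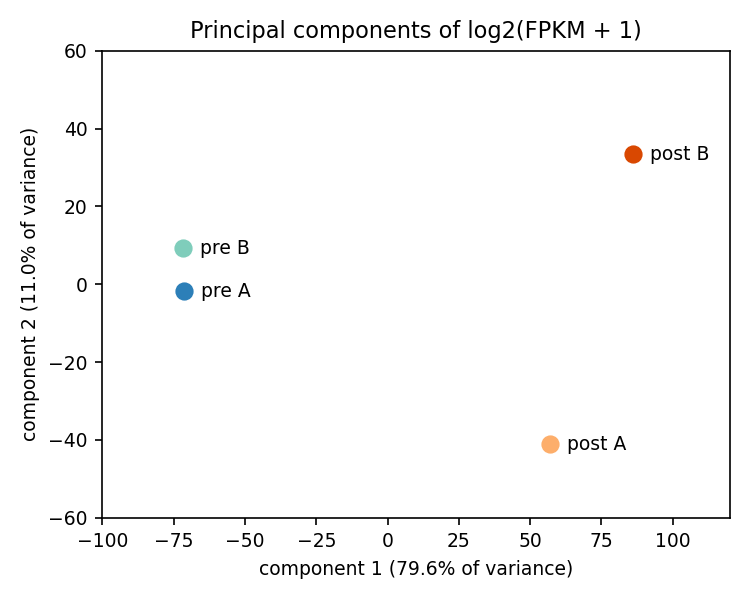
First 2 principal components of log2(FPKM + 1) over the tested genes, 1 point per library, with the percentage of variance on each axis. The pre-fertilization libraries lie at -71.4 and -71.8 on component 1, post A at 57.0 and post B at 86.1.

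The comparison of post- with pre-fertilization ovules asks which transcripts differ early after fertilization. Among genes with a symbol, NAC transcription factors, a plant family with roles in development and stress, supplied 5 of the 8 named for the largest rises. Auxin response factors, which carry the auxin signal to genes, fell more often than they rose. Only 192 tested genes have a symbol, tRNA genes left out, and 26 tested genes are NAC genes. Of these 26, 7 rose and 4 fell, while 36.5% of all tested genes were called. Neither list passed as a whole (camera adjusted p = 0.176 for NAC genes and 0.109 for auxin response factors). UGT72B18, a UDP-glycosyltransferase (an enzyme class that adds sugars to small molecules), was 99-fold higher after fertilization, at 172 ± 110 FPKM against 1.74 ± 0.993 (SD, n = 2), and the fold was 54.3 without post B and 166 without pre A. HSFB4, a class B heat stress transcription factor, fell from 44.4 ± 3.11 to 3.76 ± 2.82 FPKM (SD, n = 2), which is 11.8-fold, 25.1-fold without post A and 7.72-fold without post B. In all, 6522 of the 17849 tested genes (36.5%) passed limma's adjusted p threshold of 0.05. Of these, 3754 rose and 2768 fell, and 2136 rose and 945 fell with an absolute log2 fold change of at least 1. At an unadjusted p under 0.05 there were 8835 genes.

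The split between rises and falls turned with quantile normalization. With the authors' scaling, 57.6% of the called genes rose. Median-of-ratios scaling had factors of 1.0028 in pre A, 0.9998 in pre B, 1.0044 in post A and 1.0034 in post B. It left the values almost unchanged, so its split, 3740 rises and 2816 falls (57.0% rose), is no separate check. With quantile normalization 2956 rose and 4047 fell, so that 42.2% rose, and the median log2 fold change of all tested genes moved from 0.02 to -0.14. Called genes with an absolute log2 fold change of at least 1 still rose more often, at 1690 against 1469. No gene called with the authors' scaling was called in the opposite direction with quantile normalization. Without pre A 677 genes rose and 99 fell, and without pre B 579 rose and 74 fell, in fits that take the spread from the post-fertilization pair alone. Without post A 3828 rose and 3576 fell, and without post B 3013 rose and 2726 fell, in fits that take it from the pre-fertilization pair. Of 32 named genes that could be tested, 18 lost the call without pre A and the same 18 without pre B, and none changed direction. Those that lost the call were NAC13, HSFB4, ARF9, ARF22, NAC37, UGT84F2, UGT93A5, HSFA6B, UGT75L8, CAMKK5, LHY, TFL1A, FTA1, CHS, ACO1, CAGOLS2, FER3 and ACTIN. The 32 include DHN and RS3A, which were not called with all libraries and had no call to lose. No named gene overlapped between the groups, so leaving out a library could not turn its direction. Among those that lost the call, the log2 fold change of HSFB4 was -3.39 with all libraries, -3.46 without pre A and -3.32 without pre B.

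Of 26 tested NAC genes, 7 rose, 4 fell and 15 did not pass the test. NAC24, on chromosome 3 from 26505734 to 26507937, rose from 0.892 ± 1.04 to 32.6 ± 12.1 FPKM (SD, n = 2; log2 fold change 4.22, SE 0.48, limma adjusted p = 0.00689). NAC05 and NAC4 lie close together on chromosome 1, from 16634909 to 16637132 and from 16678912 to 16680993, and how reads shared between similar copies were counted is not given in the sources used here. NAC05 rose from 0.673 ± 0.209 to 27.2 ± 1.13 FPKM and NAC4 from 2.58 ± 0.326 to 58.9 ± 9.85 FPKM (SD, n = 2). NAC67 reached the highest level among them, 197 ± 52.5 FPKM after fertilization against 12 ± 1.16 before, and NAC13 rose from 0.347 ± 0.362 to 20.7 ± 13.3 FPKM (SD, n = 2). The 4 that fell were NAC09, NAC37, NAC30 and NAC18. NAC09 fell from 6.75 ± 2.10 FPKM to 0.131 in post A and was listed at 0 in post B. NAC37 fell from 7.53 ± 1.0 to 1.24 ± 0.359 FPKM (SD, n = 2). As a list, NAC genes did not pass (camera adjusted p = 0.176; adjusted p = 0.868 with an estimated correlation). The median log2 fold change of 1.15 was 1.83 without post A (adjusted p = 0.00888), 0.14 without post B (adjusted p = 0.718), 0.221 with no filter (adjusted p = 0.254) and 0.613 with a pseudocount of 5 (adjusted p = 0.191).

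Among 21 tested auxin response factors, 7 fell, 1 rose and 13 did not pass. ARF9, on chromosome 3 from 14022008 to 14027237, fell 7.01-fold from 52.8 ± 6.47 to 7.54 ± 4.83 FPKM (SD, n = 2; log2 fold change -2.78, SE 0.42, limma adjusted p = 0.0126), and the fold was 12.8 without post A and 4.82 without post B. ARF22, on chromosome 7 from 35086400 to 35091883, fell 5.42-fold from 24.1 ± 0.0601 to 4.45 ± 1.37 FPKM (SD, n = 2). The 1 that rose was ARF11, from 32.7 ± 0.794 to 136 ± 4.83 FPKM (SD, n = 2). The list did not pass (camera adjusted p = 0.109; adjusted p = 0.868 with an estimated correlation), and its adjusted p was 0.0497 without post A and 0.486 without post B.

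Heat stress transcription factors went both ways, with 3 of 15 higher, 3 lower and 9 not past the threshold. Besides HSFB4, HSFB4B and HSFA1B fell. HSFA6B rose from 0.170 ± 0.0701 to 5.72 ± 4.51 FPKM (SD, n = 2), with post B at 8.91 and post A at 2.53. That call was lost with a pseudocount of 5 (limma adjusted p = 0.0687), without pre A (limma adjusted p = 0.147) and without pre B (limma adjusted p = 0.137). HSFB2B and HSFA4C also rose. The camera adjusted p of the list was 0.973, and 0.988 with an estimated correlation. In the kinase cascade list, which holds mitogen-activated protein kinases and genes with CAMKK symbols taken here for kinases acting above them, 3 of 18 rose (CAMKK5, MAPK16 and MAPK12) and 3 fell (CAMKK2, MAPK3 and MAPK11). CAMKK2 fell from 30.8 ± 3.77 to 7.42 ± 0.0984 FPKM and CAMKK5 rose from 6.75 ± 1.13 to 17.0 ± 2.23 FPKM (SD, n = 2). The camera adjusted p of the list was 0.719, and 0.911 with an estimated correlation.

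UDP-glycosyltransferases were called higher as a list with a preset correlation (camera adjusted p = 0.0290) and not with an estimated one (adjusted p = 0.868 with an estimated correlation). The estimated correlation of 0.0012 was below the preset of 0.01, so correlated members do not account for that loss. With an estimated correlation the test rests on the 2 residual degrees of freedom of the fit, and could hardly pass any list. Of 30 tested members 15 rose, 3 fell and 12 did not pass, and adjusted over the list alone 17 rose and 4 fell. UGT72B18 lies on chromosome 3 from 39393244 to 39394908 (log2 fold change 5.87, SE 0.54, limma adjusted p = 0.00450), and UGT75L8 rose from 0.492 ± 0.0675 to 17.2 ± 16.6 FPKM (SD, n = 2), with 5.43 in post A and 28.9 in post B. The call of UGT75L8 was lost with a pseudocount of 5 (limma adjusted p = 0.0760), with no filter (limma adjusted p = 0.0550), without pre A (limma adjusted p = 0.152) and without pre B (limma adjusted p = 0.145). UGT84F2 fell from 8.77 ± 0.865 to 1.70 ± 0.381 FPKM and UGT93A5 from 28.7 ± 5.51 to 8.87 ± 4.37 FPKM (SD, n = 2), and UGT91H8 fell as well. The median log2 fold change of the list was 0.89. It was 0.59 without post A and 0.45 without post B, and the call was lost in both. In each of these runs 23 members were tested, and members at 1 FPKM or more only after fertilization no longer met the filter. These medians are therefore not over the same members as the 0.89. The call was also lost with no filter (median 0.10, adjusted p = 0.142), a filter of 5 FPKM (adjusted p = 0.127), a pseudocount of 5 (adjusted p = 0.0511) and on protein-coding genes only (adjusted p = 0.0545, an alternative chosen after the data were seen).

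Genes of the circadian clock, whose transcripts follow the hour of the day, gave 3 falls and 1 rise among 11 tested. LHY, a morning-phased clock factor, fell from 71.5 ± 2.56 to 34.1 ± 9.34 FPKM (SD, n = 2). LUX, an evening-phased clock factor, fell from 1.92 ± 0.0195 to 0.760 ± 0.0434 FPKM (SD, n = 2; limma adjusted p = 0.0335), a call lost without post A (adjusted p = 0.0559) and without post B (adjusted p = 0.0743). PRR59C fell and PRR37A rose. The hour of sampling is not given in the labels. The camera adjusted p of the clock list was 0.329, and 0.868 with an estimated correlation. Of 6 flowering-time genes, FTA1, of the family that promotes flowering, rose from 5.19 ± 0.356 to 11.1 ± 1.25 FPKM (SD, n = 2). TFL1A, of the family that delays it, was listed at 0 before fertilization and at 1.5 and 1.12 FPKM after (limma adjusted p = 0.0157). That call was lost with quantile normalization (limma adjusted p = 0.0504), without pre A (limma adjusted p = 0.116) and without pre B (limma adjusted p = 0.118). The camera adjusted p of that list was 0.499, and 0.868 with an estimated correlation.

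EXPA1, an expansin that loosens cell walls, rose 5.46-fold from 4.43 ± 0.515 to 24.2 ± 3.12 FPKM, while XTH1, a xyloglucan enzyme of the wall, fell 3.0-fold from 36.2 ± 1.06 to 12 ± 0.145 FPKM (SD, n = 2). Of the 4 tested members of that list CA-EXPA3 also rose. CHS, chalcone synthase at the entry to flavonoids, rose from 0.533 ± 0.259 to 4.60 ± 1.79 FPKM, and CYP93C3, of the isoflavonoid branch, fell from 2.60 ± 0.0377 to 0.30 ± 0.249 FPKM (SD, n = 2). PAL, the first enzyme of the phenylpropanoid pathway, fell too, and the remaining 3 of the 6 tested members did not pass. The test of that list pointed down (camera adjusted p = 0.961; adjusted p = 0.988 with an estimated correlation) while its median log2 fold change was 0.09, and -0.04 with quantile normalization. ACO1, which makes ethylene, rose 2.40-fold from 220 ± 27.3 to 528 ± 43.0 FPKM (SD, n = 2), the only call among 4 ethylene genes. CAGOLS2, a galactinol synthase, rose from 0.445 ± 0.226 to 2.72 ± 0.512 FPKM, and FER3, 1 of 3 ferritins, from 3.22 ± 0.0832 to 6.40 ± 1.26 FPKM (SD, n = 2). The call of FER3 was lost with no filter (limma adjusted p = 0.0562), without post B (limma adjusted p = 0.0562), without pre A (limma adjusted p = 0.157) and without pre B (limma adjusted p = 0.167). DHN, a dehydrin, was at 0.159 FPKM in pre A, listed at 0 in pre B, and at 1.18 and 4.44 FPKM in post A and post B, and did not pass (limma adjusted p = 0.0525). It passed with a pseudocount of 0.1 (limma adjusted p = 0.0291) and, in alternatives chosen after the data were seen, on protein-coding genes only (limma adjusted p = 0.0360) and on genes spanning at least 300 bp only (limma adjusted p = 0.0395).

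Genes commonly used as controls were mostly not past the threshold. Of the ribosomal protein genes 0 of 4 passed limma's test, adjusted over all genes or over the list alone, and RS3A stood at 1184 ± 29.0 FPKM before and 897 ± 81.9 after (SD, n = 2; limma adjusted p = 0.153). Of the reference genes 1 of 8 passed. It was ACTIN, which rose 4.23-fold from 57.0 ± 13.1 to 241 ± 56.5 FPKM (SD, n = 2). The test of the reference gene list pointed up (camera adjusted p = 0.961; adjusted p = 0.988 with an estimated correlation), while its median log2 fold change was -0.02, and -0.44 with quantile normalization.

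**Figure D2:**
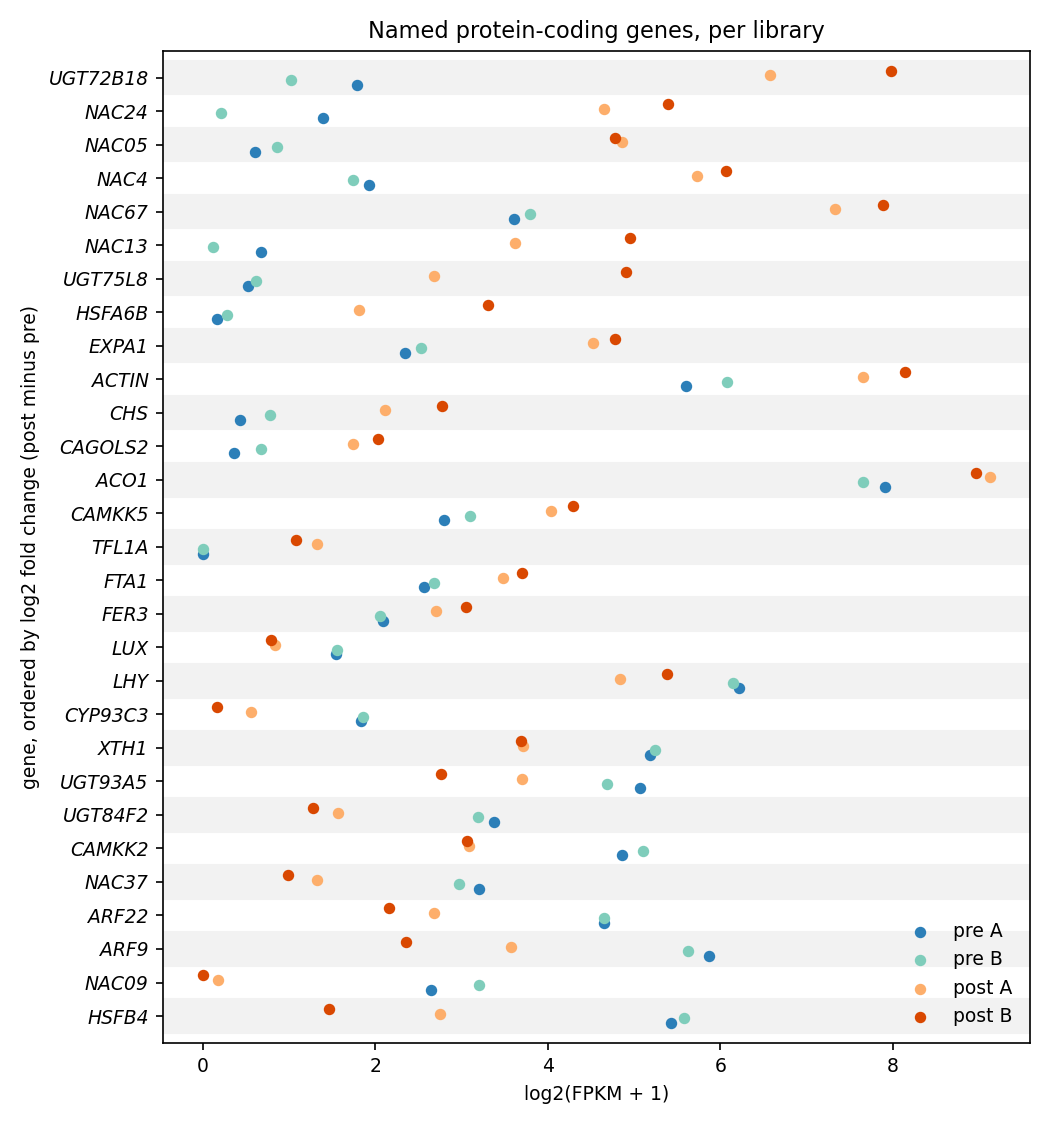
Log2(FPKM + 1) of the named protein-coding genes past limma's adjusted p of 0.05, 1 point per library, ordered by log2 fold change. The genes named for the largest changes were chosen with no overlap between the groups, and UGT72B18 and HSFB4 stand at the ends with log2 fold changes of 5.87 and -3.39.

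**Figure D3:**
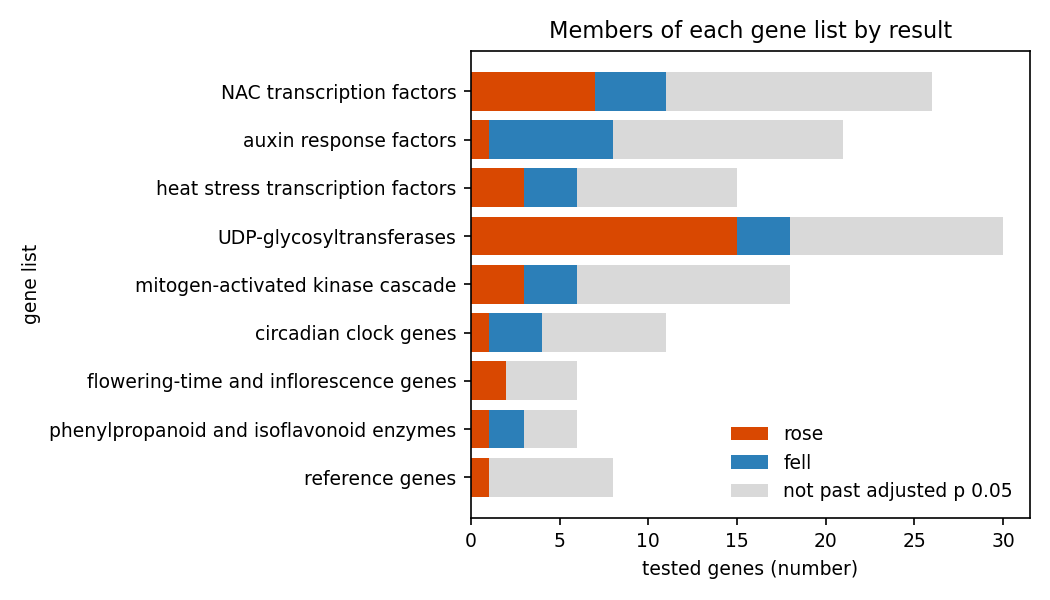
Number of tested genes in each list with at least 5 tested members, RNA classes left out, that rose, fell or did not pass limma's adjusted p of 0.05. UDP-glycosyltransferases had 15 rises and 3 falls, and auxin response factors 1 rise and 7 falls.

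Small nuclear RNA genes, whose products work in splicing, were called higher as a list with a preset correlation (camera adjusted p = 0.00964) and not with an estimated one (adjusted p = 0.868 with an estimated correlation). They made up 38.7% and 43.7% of the summed FPKM in pre A and pre B, and 50.7% and 54.1% in post A and post B, while protein-coding genes made up 36.1%, 29.5%, 27.1% and 16.9% in the same order. These are shares of FPKM and not of fragments. On genes of about 100 bp or less the FPKM that 1 fragment is worth differs between the libraries. At a span of 83 bp the lowest value above 0, taken as 1 fragment, was 374 FPKM in pre A and 381 in pre B. It was 241 in post A and 242 in post B, so at this span the worth of 1 fragment differs with group. Fold changes and list tests of RNA classes that hold such short genes are therefore confounded with this difference. How far it moved them was not tested. Of 100 tested, 19 rose and 1 fell. The median log2 fold change of 0.97 became 0.50 without post B, where the call was lost (adjusted p = 0.226), 1.53 without post A and 0.35 with quantile normalization. Of 10 tested ribosomal RNA genes 4 rose and 0 fell (camera adjusted p = 0.0290; adjusted p = 0.868 with an estimated correlation). That call was lost with a pseudocount of 5 (median 1.61, adjusted p = 0.0511), with no filter (median 1.51, adjusted p = 0.142), without pre A (adjusted p = 0.239), without post A (adjusted p = 0.758) and without post B, where too few members were left. Ribosomal RNA genes held 0.00161% of the summed FPKM in pre A, 0.0728% in pre B, 0.0256% in post A and 0.0141% in post B, so that the share was highest in a pre-fertilization library. Of 223 small nucleolar RNA genes, which guide changes to other RNAs, 15 rose and 5 fell (camera adjusted p = 0.0994; adjusted p = 0.911 with an estimated correlation). That list passed without pre B (adjusted p = 0.00424), without post A (adjusted p = 2.2e-06) and without a variance trend (adjusted p = 0.0462), and without post B its test pointed down (adjusted p = 0.486). Of 528 long non-coding RNA genes 68 rose and 68 fell (camera adjusted p = 0.176; adjusted p = 0.868 with an estimated correlation), and without post A the list was called lower (median -0.285, camera adjusted p = 0.00779). Of 8 transfer RNA genes 2 rose (camera adjusted p = 0.176; adjusted p = 0.868 with an estimated correlation). That list passed without pre A (median 8.77, camera adjusted p = 0.0108), its median was 1.27 without pre B (camera adjusted p = 0.155), and without post B its test pointed down (camera adjusted p = 0.919). Among protein-coding genes 3524 of 16463 rose and 2634 fell.

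The genes named next were listed at 0 in one group, so that no fold is given. TRNAE-CUC_17 stood at 776 and 764 FPKM in post A and post B and TRNAL-UAA_1 at 217 and 872 FPKM, both listed at 0 before fertilization. The 776 of TRNAE-CUC_17 was also the value of another transfer RNA gene in post A. LOC113784402, a long non-coding RNA gene, was listed at 0 before fertilization and at 954 and 929 FPKM after. LOC113785229, a small nucleolar RNA gene on chromosome 1 from 13428331 to 13428413, was listed at 0 before and at 482 and 1210 FPKM after, which are 2 and 5 fragments. In the other direction LOC113785586, on chromosome 2 from 2910781 to 2910863, had 374 and 1142 FPKM before fertilization, which are 1 and 3 fragments, and LOC113787910 on chromosome 7 had 173 and 369 FPKM, which are 1 and 2 fragments. Both were listed at 0 after fertilization. These fragment counts start from the lowest value above 0 at a span of 83 bp in each library, taken as 1 fragment. In pre A that value is the 374 FPKM of LOC113785586 itself.

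The labels do not say that the libraries of a group came from separate plants, so the p-values measure only the spread between these libraries, which may be technical. With 2 libraries per group the spread of each gene is estimated largely from the other genes.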

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

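The directions of the named genes held in every alternative run: of 466 values, 418 stayed on their side of the threshold, 45 lost the call, 3, all of DHN, gained it and 0 reversed. Of the 45, 39 came from leaving out a library; without pre A, 18 of 32 named genes tested lost the call, and without pre B 18 of 32. DHN and RS3A are among the 32 and had no call to lose. Each named gene had both libraries of one group above both of the other, so leaving out a library or changing the pseudocount or filter could not reverse it. The absence of reversals in those runs is therefore no evidence for the directions. The numbers of rises and falls stayed within 1.5 times under the pseudocounts, filters, scalings and variance settings. With an added limit of 1 on the absolute log2 fold change, 2136 genes rose and 945 fell, which follows from the stricter limit. Leaving out a library gave 579 to 3828 rises and 74 to 3576 falls, fewer without a pre-fertilization library, where the spread comes from the post-fertilization pair alone, and more in sum without post A, and the cause was not tested. Quantile normalization gave 2956 rises and 4047 falls, and the cause was not tested. For libraries with the same column ending, a replicate block gave 3395 rises and 2231 falls, and their deviations from the group means correlated at 0.0215, so with 2 pairs the endings are not shown to pair the libraries. The block ended the call of 1 named gene, LUX (adjusted p = 0.0703), and brought 1 more list, small nucleolar RNA, past the threshold (adjusted p = 0.0184). The 3 lists called higher became 1 with a pseudocount of 5, 1 without a filter, 0 on protein-coding genes only (chosen after the data were seen; RNA classes are then not tested) and 0 with an estimated correlation, and 0 to 4 when a library was left out. Lists called lower numbered 0, and 0 to 2 when a library was left out, the 2 being auxin response factors (adjusted p = 0.0497) and long non-coding RNA (adjusted p = 0.00779) without post A. List tests that pointed the other way had these median log2 fold changes, the ranges over all left-out libraries: heat stress factors 0.29 with a pseudocount of 5, -0.042 with a filter of 5 FPKM and -0.14 to 0.57 with a library left out; phenylpropanoid enzymes 0.39 without a filter, -0.039 with quantile normalization and -0.69 to 0.56 with a library left out; reference genes -0.44 with quantile normalization and -0.090 to 0.074 with a library left out; small nucleolar RNA 0.062 to 1.40 and transfer RNA 1.27 to 8.77 with a library left out, turned without post B. The cause was not tested for these lists. The list test with an estimated correlation rests on 2 residual degrees of freedom, so its lack of calls is no evidence against a list. The lower depth of pre B, 0.549 of pre A by the genes with low values, limits what can be said of genes listed at 0 there.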

Other observations

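All tests in this part were chosen after the results they bear on had been seen. In this part 2-fold means a difference of 1 in log2(FPKM + 1), which is less than the ratio of FPKM values for low genes.

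UDP-glycosyltransferase genes passed limma's threshold with a change of at least 2-fold, in either direction, more often than other tested genes: 14 of 30 (46.7%) against 17.2% (Fisher's exact test, two-sided, odds ratio 4.21, 95% interval 1.90 to 9.21, adjusted p = 0.00165 over 9 gene families). The test takes genes as independent, and neighbouring members may not be. With 1 member kept of each run of neighbouring members it was 12 of 26 (Fisher's exact test, adjusted p = 0.00539). It passed without post A (adjusted p = 0.00474) and without post B (adjusted p = 0.000106), and not without pre A (4 of 30 or 13.3%, against 4.45% of other genes, adjusted p = 0.193) or without pre B (3 of 30 or 10%, against 3.74%, adjusted p = 0.456), where few genes were called in all. Of NAC genes 9 of 26 (34.6%) met both limits, which did not pass after adjustment (Fisher's exact test, p = 0.0325, adjusted p = 0.146). The other 7 families had adjusted p from 0.558 to 1.

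Called genes that rose at least 2-fold lay next to each other in the order of tested genes more often than shuffled labels gave. Neighbours here are tested genes of the same sequence, unplaced sequences included, and untested genes may lie between them. Among 17835 placed genes there were 362 adjacent pairs that both rose, against a mean of 248 and a highest count of 303 in 10000 shuffles of the labels (permutation p = 0.0001, the smallest they can give). Called genes that fell at least 2-fold made 75 such pairs against a mean of 48.5 (permutation p = 0.0003). There were 5 runs of 5 neighbouring tested genes that rose. One, on chromosome 2 from 33931407 to 34128903, holds UGT71S1, and a run of 4 on chromosome 1 from 16628206 to 16703549 holds NAC05 and NAC4. A hypothesis is that neighbouring genes, tandem copies among them, changed together after fertilization. Counting of 1 gene's reads in an overlapping or adjoining gene is argued against, since 244 pairs more than 5 kb apart both rose, against a mean of 139 and a highest count of 185 in the shuffles. Reads shared between similar copies at a distance stay open, because sequences were not analysed here.

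Genes spanning at least 300 bp were listed at 0 in both pre-fertilization libraries and at 1 FPKM or more in both post-fertilization libraries 203 times, and the reverse held for 4. Of the 203, 117 were protein-coding, 22 were long non-coding RNA genes and 57 had no class in the RefSeq table. Among all 17849 tested genes 16463 were protein-coding and 457 had no class. Genes without a class were thus overrepresented in this set, and the cause was not tested. Of the 203, 167 (82.3%) were higher in post B than in post A. Lower depth before fertilization is argued against: between pre A and post A, where 1 fragment was worth nearly the same on genes of this length (ratio 0.997 at 300 to 600 bp), 286 genes were listed at 0 in pre A and at 1 FPKM or more in post A, against 34 the other way, a ratio of 8.41. Scaling between libraries is argued against too, since 74 genes would still appear if all post-fertilization values were 5 times lower. RNA from a tissue that the closed buds did not contribute, and expression that began with fertilization or with the opening of the flower, stay open and were not tested.

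Called RNA genes shorter than 150 bp could reach high FPKM on a few fragments. At a span of 83 bp the lowest value above 0, taken as 1 fragment, was 374 FPKM in pre A, 381 in pre B, 241 in post A and 242 in post B. The ratios between them hold for this span and not for longer genes. The value of 1 fragment was followed from span to span, and 97.3% of the values of up to 20 fragments came out whole within 0.02. At each span it was set from the lowest value there, divided by a whole number, so some values are whole by construction. Of 13 called small nuclear and nucleolar RNA genes under 150 bp that were listed at 0 in one group and whose fragment value was known, 69.2% held at most 3 fragments in every library and 84.6% at most 5. The value of TRNAE-CUC_17 in post A was shared by 2 transfer RNA genes and that in post B by 3, which is consistent with single fragments.

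The post-fertilization libraries differed more from each other than the pre-fertilization libraries did. Of 10543 genes with a mean of at least 10 FPKM, 519 were at least 2-fold apart between post A and post B, 456 of them higher in post B, against 149 between pre A and pre B, a ratio of 3.48. Depth is argued against, because on genes of at least 300 bp the depths of the pre-fertilization libraries differ more, while over the 10223 of these genes of that length the counts were 329 and 38. Whether post A is a mixture of RNA like that of the pre-fertilization libraries and RNA like that of post B could not be decided. Post A lay at least 2-fold outside the other 3 libraries for 73 genes, against 58 for pre A, 48 for pre B and 354 for post B. The part of the change that post A had reached, on the FPKM scale, varied more among genes that rose (lower to upper quartile 0.578 to 1.02) than among genes that fell (0.819 to 0.968). On that scale a fall is bounded by the level before fertilization and a rise is not. The contrast may therefore follow from the scale, and nothing is drawn from it. How much of the spread in either set is noise was not measured. A later stage of post B, or its handling, stays open and was not tested.

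The following genes, chosen after their values were seen, were higher in post B than in the other 3 libraries, and none passed the test between groups. HSFA6A stood at 2.72, 4.48, 12 and 92.2 FPKM in pre A, pre B, post A and post B, HSFA2 at 17.4, 24.9, 28.1 and 122 FPKM, and NAC5 at 6.88, 5.74, 9.59 and 54.9 FPKM. ACS, a gene of ethylene synthesis, stood at 4.76, 3.51, 1.94 and 22.9 FPKM. Of 26 NAC genes, 11 were at least 2-fold higher in post B than in post A and 0 were lower; of 15 heat stress factors, 6 were higher and 1 lower; of all 17849 tested genes, 877 (4.91%) were higher and 120 lower.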
